A study of Mus musculus with 20 samples.

How the data were processed

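RNA from salivary gland, small intestine and isolated colonic macrophages of mice labelled Irgm1-/- and wild type was hybridized to 20 single-colour Agilent arrays, 5 µg per sample labelled with a platinum-based Cy5 kit per the labels. Per the file headers, the arrays were of design 026655 with annotation build mm9, and the spots were read with Agilent Feature Extraction 11.5.1.1. The deposited scanner files hold intensity values on a linear scale, background-subtracted and detrended within the array by the scanner software and not normalized between arrays, and these were used here. The other deposited columns used are flags per spot (well above background, saturated, outlier), which are 0 or 1. The authors' series table holds intensity values too, whose normalization is not given in the sources used here. From the values, it is on a linear scale and quantile-normalized within each tissue (array medians of 47.6, 298.7 and 381.2 in salivary gland, small intestine and macrophages, with 100% of ranks holding the same value within 0.1%), and its lowest Spearman correlation with the scanner values of an array was 0.933. It served as an alternative only.

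Of 43020 non-control spots per array, 0.43% were marked as outliers and left out, and 0 were saturated. Spots were averaged per probe (39429 probes) after taking log2 of the processed signal. Each array was set to its 75th percentile. Where under 50% of probes were well above background on every array, as in salivary gland, the percentile was taken over probes detected on all arrays of the tissue. The design named only the percentile of the array, and the set of probes behind it was chosen from the detection flags before any call was seen. The calls under both sets were then seen together, and the other set is given as an alternative. Gene names came from a RefSeq table of assembly GRCm38.p6, used for names and for which genes are neighbours, and no coordinates were taken from it: 27508 probes matched by accession and 11921 kept the name in the file, for 23275 genes or transcripts. Symbols of list members were also looked up among the table's synonyms.

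Each gene was represented by its probe with the highest mean over all arrays, and a probe was tested in a tissue where it was well above background on at least as many arrays as the smaller group holds. The genotypes were compared in each tissue with limma 3.58.1 (lmFit and eBayes; R 4.3.3, version 1.17.8 of data.table), Benjamini-Hochberg adjustment and a threshold of 0.05, and fold changes are Irgm1-/- over wild type as labelled. Differences between tissues were tested as an interaction in a single fit of the 20 arrays with 6 group means. A set of 35 gene lists (pathways and markers of cell types), fixed before the data were examined, was tested with camera at its preset correlation of 0.01 where at least 5 members were tested, and 0 of the calls of any tissue held with an estimated correlation. The interferon list was also compared per mouse with exact two-sided permutation tests. Where a gene was not well above background on any array of a group, the fold change is given as at least the brighter group over the lowest level called well above background on each array of the dimmer group, or its own level where that was higher. Median log2 fold changes over all genes were 0.06, -0.10 and 0.09 in salivary gland, small intestine and macrophages.

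Genes were named by a rule written before the data were examined: (a) the 10 highest and 10 lowest log2 fold changes past the threshold with groups that do not overlap and detection on every array of a group, leaving out clones, predicted genes, unnamed transcripts and sex genes; (b) of each list, up to 4 members past the threshold with the largest change, or up to 2 as values where none passed; (c) a fixed set of interferon genes and targets; (d) of genes past the threshold in several tissues, the 15 with the largest smallest change; and (e) the 5 smallest p on each side of each interaction. Of the genes so chosen, 2 are not reported here.

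Each tissue was hybridized on 2 slides, each holding both genotypes, and scanned on a day of its own, so tissue and scan day cannot be separated. Slide served as a block in an alternative, and values were recomputed within slides. The labels number the mice in each group. Slides match by number in every tissue, and ages match in small intestine and macrophages but not in salivary gland. After removing group means, mice of the same number correlated across genes by 0.19, 0.24 and 0.39 in small intestine and by 0.5, 0.29 and 0.66 in macrophages, so the numbers may pair samples there. In salivary gland the correlations were 0.21, -0.10, -0.52 and 0.44. The main fits of every tissue ignored the number, and it served as a block only in an alternative. Animal numbers carried by the deposited files tie small intestine and macrophages to 6 shared animals, and age, sex and genotype matched for 6 of the 6. Labels and sex genes were checked: Xist was well above background on 4 of 4 female arrays and 0 of 2 male arrays of small intestine and of macrophages, and Ddx3y on 2 of 2 male and 0 of 4 female arrays of each.

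The fits were tested on simulated data, drawn as independent normal values per gene with the means and spreads of each tissue. For the interaction the spread was pooled over all tissues. No correlation between genes, mice or slides was simulated, so the counts of false calls hold for such noise only. Of genes given a log2 change of 1 and of 2, 68% and 91% were recovered in salivary gland (9580 genes), 40% and 75% in small intestine (15004 genes) and 4% and 59% in macrophages (16413 genes), with 12, 11 and 5 false calls. For the interaction of salivary gland with small intestine (8774 genes) 27% and 84% were recovered with 6 false calls. The alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median, no filter, detection on every array, the mean of all probes, a fit of all arrays, an intensity trend with robust variances, mouse number or slide as a block, the authors' series table, sex as a covariate, females only, animal as a random block, the other set of probes behind the percentile, leaving out each array, and, for lists, an estimated correlation and fry. The pancreatic list was also left out of the genes tested, which, like the other set of probes, was chosen after seeing the data. Transcripts without a gene name were left out of the main fits, and were fitted and are summarised apart. The number of arrays limits the precision. P-values of the limma fits of single genes and of the permutation tests per mouse measure the spread between these mice. Those of camera at its preset correlation and of Fisher's exact test do not. Camera at that setting takes the genes of a list as nearly independent, and Fisher's test takes genes as independent.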

Results

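Gene expression was measured on 20 single-colour microarrays with RNA from 3 tissues of C57BL/6 mice kept free of specific pathogens. Irgm1 encodes an immunity-related GTPase that interferons induce and that acts in autophagy and in defence against microbes inside cells. Salivary gland was taken from 4 mice labelled Irgm1-/- and 4 wild type mice. Small intestine (whole duodenum) and macrophages isolated from the colon were taken from 3 mice of each genotype. The mice were 6 to 9 weeks old. The question, from the series title, was which genes, interferon-induced genes among them, differ between the genotypes in more than a single tissue. The 75th percentile of intensity ran from 134 to 1083 on the salivary gland arrays, from 2563 to 5070.2 on the small intestine arrays and from 888 to 2101 on the macrophage arrays. In small intestine the brightness of the arrays ran together with genotype. The percentile was 5070.2, 4234.2 and 4913.6 on the Irgm1-/- arrays and 2562.7, 3529 and 2993.4 on the wild type arrays. In salivary gland the groups overlapped, but each Irgm1-/- array was brighter than the wild type array of the same number. The percentile there was 1082.7, 373.3, 382.7 and 159.5 on Irgm1-/- replicates 1 to 4 and 350.1, 274.1, 176.8 and 134.3 on wild type replicates 1 to 4. More probes were also well above background on each (48.7%, 36.7%, 37.3% and 27.2% against 36.1%, 32.9%, 28.5% and 25.2%). Between 25.2% and 48.7% of probes were well above background in salivary gland, between 52.6% and 62.2% in small intestine and between 57.1% and 74.4% in macrophages. The number of arrays limits the precision. Genotype ran together with age in salivary gland (9 weeks against 6 and 7) and with sex in the other tissues, where the Irgm1-/- groups held 2 males and 1 female each and the wild type groups were all female.

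Irgm1 itself was higher, not lower, on the arrays labelled Irgm1-/-. In salivary gland it rose by 2.64 on the log2 scale (SE 0.23, n = 4 per group, adjusted p = 0.000405), and in small intestine by 1.16 (SE 0.13, n = 3 per group, adjusted p = 0.0394). In macrophages the difference was 0.88 (SE 0.31, n = 3 per group, adjusted p = 0.262) and did not pass. The gene's other probe differed by 2.26, 1.18 and 1.16 in the same order. These levels go against the genotype label. The deleted part of the gene is not given in the sources used here, and a probe outside it checks nothing, so the groups are called labelled Irgm1-/- and every direction follows the label. Within the 2 slides of each tissue the difference was 3.07 and 2.21 in salivary gland, 1.20 and 1.14 in small intestine, and 0.96 and 0.73 in macrophages. In small intestine the call ended with the slide as a block (adjusted p = 0.0646), with the mouse number as a block (adjusted p = 0.182) and without any single array other than wild type replicate 1 (adjusted p = 0.284, 0.206 and 0.322 without Irgm1-/- replicates 1, 2 and 3, and 0.13 and 0.218 without wild type replicates 2 and 3). Over all alternatives the adjusted p lay between 0.0195 and 1. In macrophages the mouse number as a block gave an adjusted p of 0.0465, within a range of 0.0465 to 0.761 over the alternatives.

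In salivary gland, genes induced by interferons rose in the mice labelled Irgm1-/-. The apolipoprotein L genes Apol9b (log2 fold change 5.38, SE 0.21, n = 4 per group) and Apol9a (4.46, SE 0.22), Ifit3, which binds viral RNA in a complex with its relatives (4.71, SE 0.33), and Oas1a, an enzyme that makes the activator of RNase L (4.48, SE 0.20), were among the genes with the largest changes. Apof, a lipid transfer inhibitor, rose by 4.29 (SE 0.29), and the oligoadenylate synthetase family members Oas1f and Oasl1 rose by 4.22 (SE 0.23) and 4.15 (SE 0.35). Genes that were not well above background on any wild type array are given as lower bounds: Ifit3b was at least 14.3-fold higher, Oas2 at least 12.6-fold, Irf7, a transcription factor for interferon genes, at least 11.7-fold and Gbp3 at least 9.51-fold. Of 9594 genes tested, 277 changed, 254 of them higher and 23 lower, and 200 of these changed at least 2-fold.

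The type I interferon-induced genes rose as a group in salivary gland, with 28 of 31 tested members past the threshold, all higher, and 28 when adjusted over the list alone. Their median log2 fold change was 2.60, or 2.54 with the genes dim in wild type at their bound (limma camera, adjusted p = 1.22e-35; adjusted p = 0.247 with an estimated correlation). The ubiquitin-like modifier Isg15 rose by 3.45 (SE 0.28), its protease Usp18 by 3.37 (SE 0.15) and Oasl2 by 3.80 (SE 0.27). Immunity-related GTPases and guanylate-binding proteins, which act on vacuoles that hold microbes, rose in 7 of 10 members (8 adjusted over the list alone; median 3.21, adjusted p = 6.13e-09; adjusted p = 0.32 with an estimated correlation). Igtp rose by 3.66 (SE 0.34), Tgtp2 by 3.34 (SE 0.41), Gbp2 by 3.26 (SE 0.45) and Irgm2 by 2.50 (SE 0.30), and Irgb10, listed as Gm12250, was at least 9.53-fold higher. Genes of MHC class I antigen processing rose in 13 of 16 members (14 adjusted over the list alone; median 1.92, adjusted p = 1.43e-15; adjusted p = 0.32 with an estimated correlation). Among them were the light chain B2m (3.35, SE 0.24), the immunoproteasome subunits Psmb8 (3.10, SE 0.28) and Psmb9 (3.02, SE 0.33) and the transactivator Nlrc5 (3.10, SE 0.34), and H2-K1, a class I heavy chain, rose by 2.28 (SE 0.21). Another probe of Nlrc5 differed in the opposite direction. Ifit1, Iigp1, Cxcl9, Ifnb1 and Ifng were too dim in salivary gland to be tested.

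Chemokines rose in 5 of 9 members in salivary gland (7 adjusted over the list alone; median 1.53, adjusted p = 8.61e-06; adjusted p = 0.32 with an estimated correlation). Cxcl10, which draws activated T cells, was at least 3.97-fold higher (log2 1.82, adjusted p = 0.0674, with the mean of all its probes) and Ccl12 at least 6.18-fold, while Ccl5 rose by 2.66 (SE 0.35) and Ccl19 by 1.68 (SE 0.34). Nucleic acid sensing genes rose in 6 of 15 members (7 higher and 2 lower adjusted over the list alone; median 0.42, adjusted p = 0.0181; adjusted p = 0.53 with an estimated correlation), with Ifi204 up by 2.81, Ifi211 by 2.70, Samhd1 by 1.72 and Ifi203 at least 3.88-fold. With the mean of all probes Ifi203 was at 0.55 (adjusted p = 0.242) and Samhd1 at 0.68 (0.141), and neither passed. The list did not pass with detection on every array (median 0.0915, adjusted p = 0.0921) or with the mouse number as a block (0.057). Inflammatory cytokines and NF-kB targets rose in 3 of 10 members (6 adjusted over the list alone; median 0.82, adjusted p = 0.00465; adjusted p = 0.32 with an estimated correlation). They were Socs1, at least 2.32-fold higher, Il18bp, which binds interleukin 18 (2.43), and Tnip1 (1.14). The call of Socs1 ended under normexp (log2 1.497, adjusted p = 0.05) and that of Tnip1 with no filter (0.104). MHC class II genes had a median of 0.998 with H2-DMb1 (1.75) as the single member past the threshold of 7 (4 adjusted over the list alone; adjusted p = 0.00349; adjusted p = 0.53 with an estimated correlation). H2-DMb1 was at 0.58 with the mean of all probes (adjusted p = 0.197), and its call also ended with no filter (0.162) and in the fit of all 20 arrays (0.0523). The 3 tested members of the interferons list did not pass, with Ifnab at -0.33 and Ifnl3 at -0.28. Immediate early and heat shock genes shifted up without any of 11 members past the threshold (5 adjusted over the list alone; median 0.46, adjusted p = 0.0082; adjusted p = 0.53 with an estimated correlation), Egr1 at 1.07 and Hspa1a at 0.77 having the largest differences. Autophagy and mitophagy genes (median 0.0042, 0 of 27 past the threshold, 0 adjusted over the list alone, adjusted p = 0.948) and oxidative phosphorylation genes (median 0.026, 0 of 35, 0 adjusted over the list alone, adjusted p = 0.678) did not pass.

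Among lists of immune cell markers in salivary gland, resident macrophage markers rose in 7 of 12 members (10 adjusted over the list alone; median 0.86, adjusted p = 1.59e-06; adjusted p = 0.247 with an estimated correlation), among them the complement genes C1qa (1.67), C1qc (1.56) and C1qb (1.32) and the folate receptor Folr2 (0.99). Granzyme A (Gzma) of T and NK cells rose by 2.50, the monocyte markers Plac8 and Ly6c1 by 3.36 and 2.52, and the dendritic cell markers Itgax and Irf8 by 1.94 and 1.41, though the 3 lists that hold them did not pass (medians 0.51, -0.14 and 0.08; adjusted p = 0.176, 0.522 and 0.3). B and plasma cell markers did not pass either (median 0.02, adjusted p = 0.201). Under normexp Itgax, Irf8 and Folr2 were at 0.76, 0.80 and 0.40 and did not pass (adjusted p = 0.129, 0.0771 and 0.387). Ly6g was at least 3.3-fold higher. The epithelial factor Elf3 rose by 0.72 and the peptide hormone Cck by 0.999.

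Fewer genes were lower in salivary gland, and by less. Pttg1 (securin) fell by 1.73 (SE 0.33), the eosinophil ribonuclease Ear2 by 1.67 (SE 0.25), the mitochondrial transhydrogenase Nnt by 1.66 (SE 0.12) and the synaptic protein Erc2 by 1.56 (SE 0.32). With the mean of all probes the calls of Nnt (-1.11, adjusted p = 0.148) and Erc2 (-0.89, 0.369) ended. Guk1 fell by 0.89, Pex11g by 0.80, Phyh by 0.79 and Atic, for which another probe differed in the opposite direction, by 0.77. With the mean of all probes Pex11g was at -0.46 and Atic at -0.23, and neither passed (adjusted p = 0.254 and 0.334). Salivary acinar markers shifted down (median -0.55, adjusted p = 0.000154; adjusted p = 0.332 with an estimated correlation), with 2 of 19 members past the threshold and 5 adjusted over the list alone: Smgc, a mucin-like product of the gland, fell by 0.87 and lactoperoxidase (Lpo) by 0.59, the latter at -0.35 under normexp (adjusted p = 0.128) and -0.39 under quantile normalization (0.244). Derl3, kept in the plasma cell list and active in protein quality control, fell by 0.83. The median of the acinar markers was -1.08 on the first slide and -0.08 on the second. Goblet cell markers (median -0.43, adjusted p = 0.031; adjusted p = 0.53 with an estimated correlation) and pancreatic acinar markers (median -0.41, adjusted p = 0.0216; adjusted p = 0.53 with an estimated correlation) shifted down with no member past the threshold over all genes. The goblet cell call ended with the slide as a block (adjusted p = 0.0518, within a range of 0.00141 to 0.53 over the alternatives). Its median within slides was -1.09 and 0.07, and it also ended under quantile normalization (adjusted p = 0.0732) and normexp (adjusted p = 0.117).

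Within slides, 290 genes changed on the first and 147 on the second salivary gland slide. The interferon list's median was 2.94 and 2.13, that of the GTPases 4.15 and 2.27, that of MHC class I 2.19 and 1.53, that of MHC class II 1.82 and 0.13, that of chemokines 2.12 and 0.82 and that of resident macrophages 0.87 and 0.83. With the slide as a block 641 genes changed, 442 higher and 199 lower. Of the 277 calls, 156 stayed under normexp, 144 with each array scaled to its median, 117 with no filter and 195 with the mean of all probes. The count fell to 148 without Irgm1-/- replicate 2, to 161, 137 and 146 without wild type replicates 1, 2 and 4, and to 153 with each array scaled to its median, under which Ear2, Guk1, Smgc, Derl3, Pex11g, Phyh and Atic did not pass. Nor did C1qb, Irf8, Folr2 and Elf3 (adjusted p = 0.0998, 0.0628, 0.346 and 0.73) or Cck, Tnip1, Lpo and Plac9a (0.362, 0.186, 0.993 and 0.238) under that scaling. Leaving out 1 array ended the calls of Smgc, Lpo, Atic and Folr2 for 7 of the 8 arrays, with log2 fold changes of -0.96 to -0.72, -0.68 to -0.55, -0.89 to -0.67 and 0.88 to 1.21. It ended the call of Guk1 for 6 arrays (-1.04 to -0.80). For 5 arrays it ended the calls of Pttg1 (-2.08 to -1.49), Erc2 (-1.75 to -1.31), C1qb (1.13 to 1.51), H2-DMb1 (1.39 to 1.99) and Samhd1 (1.37 to 1.94).

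**Figure D1:**
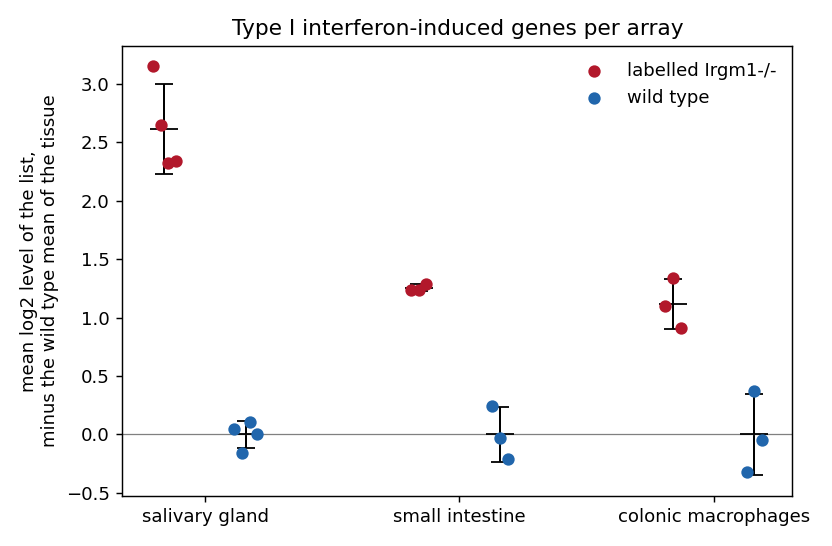
Mean log2 level of the tested type I interferon-induced genes on each array, relative to the wild type mean of the same tissue, for wild type mice and mice labelled Irgm1-/-. Points are arrays and black bars are the mean and SD of a group. Every array labelled Irgm1-/- lay above every wild type array of its tissue, at means of 2.61 in salivary gland, 1.26 in small intestine and 1.12 in colonic macrophages.

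In small intestine the same kind of genes was higher in mice labelled Irgm1-/-, with smaller differences. Ifi44, an interferon-induced protein, rose by 3.41 (SE 0.17, n = 3 per group), Oas2 by 3.40 (SE 0.24), Usp18 by 2.68 (SE 0.24), Ifit2 by 2.54 (SE 0.15), Ifit3b by 2.42 (SE 0.18), Phf11d by 2.33 (SE 0.15) and Ifit3 by 2.27 (SE 0.19). The largest change belonged to Thg1l, a tRNA guanylyltransferase, which was at least 18.1-fold higher and not well above background on any wild type array. The sensor family member Ifi213 was at least 2.18-fold higher, the immunoglobulin segment Igkv8-16 at least 3.15-fold and Cblif, the gastric intrinsic factor, at least 1.58-fold. Under normexp these 4 were at 3.16, 0.41, 0.87 and 0.34 on the log2 scale and did not pass (adjusted p = 0.192, 0.68, 0.589 and 0.745), each below its bound. Ifi213 did not pass with the mean of all probes either (1.57, adjusted p = 0.218). Of 15078 genes tested, 28 rose and 0 fell (limma; 1066 genes had an unadjusted p under 0.05), and 15 of the 28 were in the interferon list.

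Type I interferon-induced genes had a median log2 fold change of 1.08 in small intestine, with 15 of 46 members past the threshold and 34 adjusted over the list alone (adjusted p = 5.65e-59; adjusted p = 0.121 with an estimated correlation). Isg15 rose by 1.62 (SE 0.19). Immunity-related GTPases and guanylate-binding proteins had a median of 1.23 with Tgtp1 (1.63, SE 0.18) past the threshold out of 18 members and 10 adjusted over the list alone (adjusted p = 7.28e-21; adjusted p = 0.121 with an estimated correlation). The call of Tgtp1 ended under normexp (0.51, adjusted p = 0.59), with no filter (0.063), in the fit of all 20 arrays (0.107) and with an intensity trend (0.0741). It also ended with the other set of probes behind the percentile (0.0571), an alternative chosen after seeing the data, and with the mouse number as a block (0.0828). Several interferon targets did not pass over all genes: Irf7 differed by 1.84 (adjusted p = 0.359), Cxcl10 by 1.61 (0.098), Iigp1 by 1.55 (0.0524), Oasl2 by 1.49 (0.0933), Igtp by 1.36 (0.569), Cxcl9 by 1.35 (0.621), Ifit1 by 1.09 (0.535) and Irgm2 by 1.03 (0.664). Psmb8 differed by 0.56, Gbp2 by 0.46 and H2-K1 by 0.02, and Ifnb1 and Ifng were too dim to be tested. MHC class I genes shifted up slightly, with 0 of 18 members past the threshold (0 adjusted over the list alone; median 0.16, adjusted p = 0.00048; adjusted p = 0.513 with an estimated correlation), the median being -0.03 and 0.26 within slides.

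Other lists that shifted up in small intestine did so by small medians. Chemokines had 0 of 14 members past the threshold and 5 adjusted over the list alone (median 0.33, adjusted p = 5.81e-05; adjusted p = 0.387 with an estimated correlation), Ccl3 differing at least 1.83-fold. Nucleic acid sensing genes had Ifi204 (1.86) past the threshold of 20 members (4 adjusted over the list alone; median 0.16, adjusted p = 3.6e-05; adjusted p = 0.36 with an estimated correlation). Resident macrophage markers had a median of 0.29 (adjusted p = 2.61e-07; adjusted p = 0.36 with an estimated correlation), with Siglec1 at least 2.53-fold different and not past the threshold. Neutrophil markers (median 0.26, adjusted p = 0.0204; 0.36 with an estimated correlation), inflammatory cytokines and NF-kB targets (0.24, adjusted p = 0.00714; 0.418 with an estimated correlation) also shifted up. MHC class II genes (0.33, adjusted p = 0.0364, or 0.513 with an estimated correlation) and smooth muscle, fibroblast and endothelial markers (0.18, adjusted p = 0.0207, or 0.513 with an estimated correlation) did as well, with no member of these 4 lists past the threshold over all genes. Leaving out 1 array gave MHC class II medians of 0.0985 to 0.538 and ended the call for 4 of 6 arrays. It gave stromal medians of 0.038 to 0.296 and ended that call for 3 of 6. The neutrophil and inflammatory calls ended under normexp, at medians of 0.0175 and -0.0903.

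Some lists of intestinal cell types shifted down in small intestine, each with 0 members past the threshold, whereas general epithelial markers (median -0.26, adjusted p = 0.102) and intestinal stem cell markers (-0.05, adjusted p = 0.382) did not pass. Paneth cell and antimicrobial genes had a median of -0.60 (10 of 15 lower adjusted over the list alone; adjusted p = 3.28e-08; adjusted p = 0.418 with an estimated correlation), with the defensins Defa-rs7 at -1.11 and Defa29 at -0.73. Their call ended under quantile normalization (median -0.0875, adjusted p = 0.0954). Oxidative phosphorylation genes had a median of -0.38, all 35 being below 0 (adjusted p = 3.28e-08; adjusted p = 0.513 with an estimated correlation). Enteroendocrine and tuft cell markers (median -0.37, adjusted p = 0.02; 0.513 with an estimated correlation) and mast cell and eosinophil markers (-0.81, adjusted p = 0.0262; 0.418 with an estimated correlation) shifted down too. Absorptive enterocyte markers (-0.36, adjusted p = 0.0103; 0.469 with an estimated correlation) and goblet cell markers (-0.23, adjusted p = 0.02; 0.574 with an estimated correlation) did as well. Under quantile normalization the test of the enterocyte and goblet cell lists turned to the upward side, at medians of -0.03 and -0.04 (adjusted p = 0.824 and 0.745). The same calls ended under normexp (adjusted p = 0.312 and 0.626) and with no filter (0.556 and 0.436). With the slide as a block the mast cell and enteroendocrine calls ended (adjusted p = 0.0558 and 0.0617), and with sex as a covariate the enteroendocrine call did (median -0.16, adjusted p = 0.594). Within slides, the medians were 0.98 and 1.21 for the interferon list, 0.84 and 1.37 for the GTPases, 0.39 and 0.53 for chemokines, -0.75 and -0.18 for oxidative phosphorylation, -0.89 and -0.41 for the Paneth cell list and -0.84 and -0.13 for the enteroendocrine list.

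Within slides, 14 genes changed on the second small intestine slide, the first holding 1 array of each genotype. The count was 2, 2 and 3 without Irgm1-/- replicates 1, 2 and 3, and 47, 11 and 4 without wild type replicates 1, 2 and 3. It was 3 under normexp, 1 with the mouse number as a block, 27 with the slide as a block, 1 with sex as a covariate and 2 among females. Under normexp Oas2, Ifit3b and Phf11d alone passed, and with the mouse number as a block or sex as a covariate Thg1l alone. The interferon list's mean, relative to wild type, was 1.29 on the female Irgm1-/- array and 1.24 and 1.24 on the male ones. The calls lost with sex as a covariate thus do not mean that the list's difference was smaller in the female. Of the 28 calls, 22 stayed with each array scaled to its median, 22 with no filter and 19 in the fit of all 20 arrays.

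In the colonic macrophage samples, few interferon-induced genes passed and the genes with the largest changes were digestive enzymes of the exocrine pancreas, lower in mice labelled Irgm1-/-. The elastase Cela2a was at least 739-fold lower (n = 3 per group), the trypsinogen Try4 at least 665-fold, carboxypeptidase B1 (Cpb1) at least 189-fold and the lipase-related Pnliprp1 at least 185-fold. On the log2 scale the trypsinogens Prss2 and Try5 changed by -10.77 (SE 0.59) and -9.11 (SE 0.57). The amylase Amy2a5 changed by -8.67 (SE 0.49) and the lipase Pnlip by -7.75 (SE 0.48). Reg1 and Gp2, both abundant in pancreatic acini, were at least 90-fold and 49.7-fold lower. Higher were Oas3 (3.54, SE 0.40), Oas2 (2.60, SE 0.38), the helicase-related sensor Dhx58 (2.18, SE 0.29) and the transcription factor Mycl (at least 4.47-fold), which were the 4 genes that rose. Of 16563 genes tested, 39 changed, 4 higher and 35 lower, and 15 of the 39 were in the pancreatic acinar list.

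Type I interferon-induced genes had a median log2 fold change of 0.92 in macrophages, with 3 of 44 members past the threshold and 24 adjusted over the list alone (adjusted p = 3.93e-19; adjusted p = 0.312 with an estimated correlation). Several members had differences that did not pass over all genes: Oasl2 2.88 (adjusted p = 0.0507), Usp18 2.54 (0.09), Ifit1 2.29 (0.112), Ifit3 1.75 (0.137), Irf7 1.74 (0.0646) and Isg15 1.02 (0.229). With the mouse number as a block these 6 passed (adjusted p = 0.012, 0.013, 0.0123, 0.0109, 0.0109 and 0.035). Igtp differed by 1.11 and Irgm2 by -0.02, and the immunity-related GTPases and guanylate-binding proteins did not pass as a list (median 0.06, 0 of 14, 0 adjusted over the list alone, adjusted p = 0.529). Gbp2 (-0.40), Iigp1 (0.32), Cxcl9 (0.35), Cxcl10 (0.33), Psmb8 (0.34), H2-K1 (0.20) and Ifng (-0.25) did not pass, nor did Ifnb1, which encodes interferon beta (-1.43, adjusted p = 0.0791, or 0.0136 with the mouse number as a block). MHC class I genes shifted up with 0 of 17 members past the threshold (0 adjusted over the list alone; median 0.32, adjusted p = 0.0451; adjusted p = 0.62 with an estimated correlation), a call that ended with each array scaled to its median (adjusted p = 0.0725) and with sex as a covariate (median 0.07, adjusted p = 0.677).

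Markers of other cell types moved with the genotype in the macrophage samples. Epithelial markers were also bright in both genotypes. Array medians relative to the percentile were 3.14 to 4.15 for the goblet cell list and 2.06 to 3.44 for the general epithelial list. Those of resident macrophage markers were -1.79 to 0.26, though levels of different lists are not directly comparable. Which cells the differences in these samples came from, those of the interferon list included, was not tested. Pancreatic acinar genes fell in 15 of 19 members (17 adjusted over the list alone; median -6.24, adjusted p = 4.9e-46; adjusted p = 0.312 with an estimated correlation). The array medians of this list were -2.43, -2.24 and -1.71 in Irgm1-/- replicates 1 to 3 and 6.62, 5.06 and 4.22 in wild type replicates 1 to 3. Smooth muscle, fibroblast and endothelial markers shifted down, with actin Acta2 (-2.72, SE 0.41) past the threshold of 17 members and 12 adjusted over the list alone (median -1.24, adjusted p = 1.42e-12; adjusted p = 0.312 with an estimated correlation). Resident macrophage markers also shifted down (0 of 18 past the threshold, 0 adjusted over the list alone; median -1.05, adjusted p = 4e-05; adjusted p = 0.577 with an estimated correlation), with Cd163 at -1.99 and C1qa at -1.56. This call ended with sex as a covariate (median -0.54, adjusted p = 0.0592), and leaving out 1 array moved its median from -1.55 to -0.623. Goblet cell markers shifted up (7 of 12 adjusted over the list alone; median 1.04, adjusted p = 1.42e-06; adjusted p = 0.37 with an estimated correlation), with Retnlb at 1.69 and the trefoil peptide Tff3 at 1.46. So did general epithelial markers (median 0.54, adjusted p = 0.0236; 0.668 with an estimated correlation), intestinal stem cell markers (0.78, adjusted p = 0.000613; 0.312 with an estimated correlation) and salivary duct markers (0.31, adjusted p = 0.0339; 0.312 with an estimated correlation). With sex as a covariate the general epithelial markers did not pass (median -0.03, adjusted p = 0.955). Cell cycle genes had a median of 0.74 with all 18 above 0 (adjusted p = 3.82e-07; adjusted p = 0.312 with an estimated correlation). Cholesterol biosynthesis genes had a median of 0.93 (8 of 18 higher adjusted over the list alone; adjusted p = 4.21e-09; adjusted p = 0.577 with an estimated correlation), with Idi1 at 1.54 and Cyp51 at least 1.2-fold different.

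**Figure D2:**
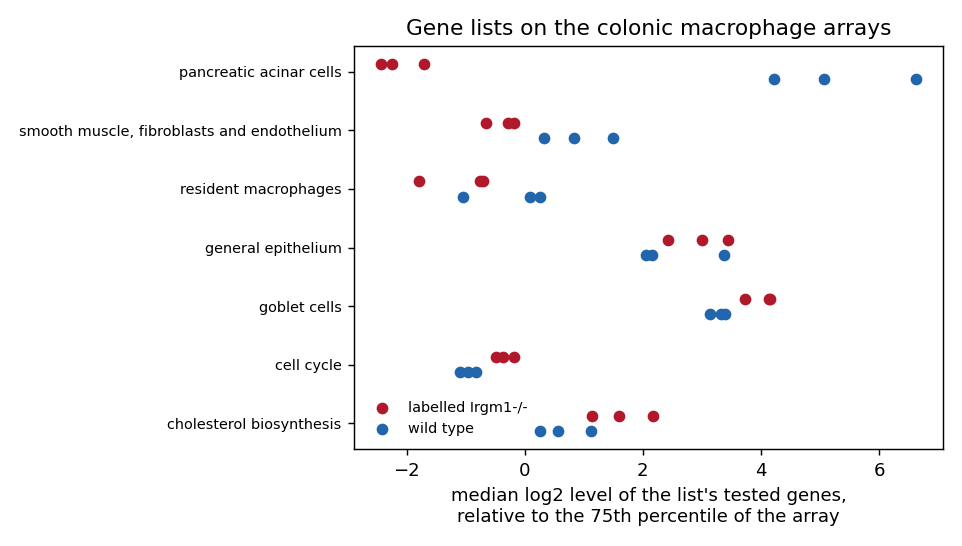
Median log2 level of the members of 7 lists on each colonic macrophage array, relative to the 75th percentile of the array, for wild type mice and mice labelled Irgm1-/-; points are arrays, and levels are to be compared between genotypes within a list only. The pancreatic acinar list lay between 4.22 and 6.62 on the wild type arrays and between -2.43 and -1.71 on the Irgm1-/- arrays.

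A further group of lists shifted in macrophages with 0 members past the threshold. Oxidative phosphorylation genes had a median of 0.42 (adjusted p = 0.000477; 0.672 with an estimated correlation), inflammatory cytokines and NF-kB targets of -0.29 (adjusted p = 0.00639; 0.577 with an estimated correlation). Immediate early and heat shock genes had a median of -0.22 (adjusted p = 0.0279; 0.668 with an estimated correlation) and unfolded protein and integrated stress response genes of -0.17 (adjusted p = 0.0357; 0.577 with an estimated correlation). The latter pair ended under normexp (adjusted p = 0.115 and 0.134), and the oxidative phosphorylation call ended with sex as a covariate (adjusted p = 0.334). Amy1, an amylase of the salivary acinar list, fell by 5.23 (SE 0.36). Within slides, the interferon list's median was 0.97 and 0.86, the pancreatic list's -6.74 and -5.18, the stromal list's -1.26 and -1.03, the resident macrophage list's -1.02 and -0.87, the goblet cell list's 1.22 and 0.43, the cell cycle list's 0.67 and 0.83 and the cholesterol list's 0.93 and 0.93.

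Within slides, 30 genes changed on the first macrophage slide, the second holding 1 array of each genotype. With the slide as a block 38 genes changed, 7 higher and 31 lower, but Oas2, Mycl and Acta2 did not pass (adjusted p = 0.0794, 0.0627 and 0.0707). The mouse number as a block gave 1313 genes, 363 higher and 950 lower. The count was 20 without wild type replicate 2, 8 with the pancreatic acinar list left out (1 higher, 7 lower; chosen after seeing the data). It was 10 with sex as a covariate, all lower and all among the main calls. With that covariate Oas2, Oas3 and Dhx58 did not pass (adjusted p = 0.622, 0.348 and 0.622). Nor did the pancreatic genes Cpb1, Cel, Ctrb1, Gp2 and Reg1 (adjusted p = 0.0524, 0.0541, 0.0915, 0.0541 and 0.143). The covariate sets the single female Irgm1-/- array against wild type. The pancreatic list's median was -1.71 on that array and 4.22 to 6.62 on the wild type arrays, so these lost calls do not mean that the list's difference vanished. Amy2a5 and Amy1 did not pass in the fit of all 20 arrays (0.0726 and 0.383), where their fold changes are those of the main fit and only the estimate of the spread differs. The count was 343 under normexp and 209 with each array scaled to its median. Leaving out any single array ended the calls of Oas2 (2.23 to 2.81) and Mycl (2.07 to 2.66; 1.35 under normexp, adjusted p = 0.064), and for 5 of the 6 arrays it ended those of Dhx58 (2.02 to 2.44) and Acta2 (-2.96 to -2.25). The call of Dhx58 also ended under normexp (adjusted p = 0.0676), with no filter (0.0532), among females (0.0547) and with the pancreatic list left out (0.0611). The call of Oas3 kept its side of the threshold without any single array but ended among females (adjusted p = 0.0624).

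The tissues shared a set of higher genes. Of genes tested in both salivary gland and small intestine, 17 were higher in both, against 0.539 for independent calls (Fisher's exact test, one-sided, p = 1.27e-24), and 18 of the 20 small intestine calls tested in salivary gland were higher there at an unadjusted p under 0.05. Salivary gland and macrophages shared 2 (0.0538 for independent calls; Fisher's exact p = 0.000719), and small intestine and macrophages, which came from the same 6 mice, shared 3 (0.00814; Fisher's exact p = 3e-08). Fisher's test counts genes as independent, so these p-values do not measure the spread between mice. No gene was lower in more than 1 tissue. Altogether 18 genes were higher in at least 2 tissues, and 2, Oas2 and Dhx58, in all 3. Among those in salivary gland and small intestine were Usp18 (3.37 and 2.68), Ifit3 (4.71 and 2.27), the antiviral radical enzyme Rsad2 (3.94 and 2.05), Rtp4 (3.08 and 1.76), Xaf1 (3.32 and 1.79), Phf11b (2.80 and 1.73), Phf11d (1.83 and 2.33), Ifi204 (2.81 and 1.86), Isg15 (3.45 and 1.62), the membrane restriction factor Ifitm3 (2.14 and 1.19) and Irgm1 (2.64 and 1.16). In macrophages these 11 had differences of 2.54, 1.75, 0.99, 1.72, 1.31, 0.69, 0.91, -0.59, 1.02, -0.62 and 0.88 and did not pass. In macrophages, with the mouse number as a block, 8 of them passed: Usp18, Ifit3, Rsad2 and Rtp4 (adjusted p = 0.013, 0.0109, 0.0247 and 0.0208) and Xaf1, Phf11d, Isg15 and Irgm1 (0.0289, 0.0394, 0.035 and 0.0465). Oas3 rose in small intestine (2.04) and macrophages (3.54) and was too dim to be tested in salivary gland.

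The number of genes in at least 2 tissues was 2, 2 and 2 without small intestine Irgm1-/- replicates 1, 2 and 3, and 29, 6 and 2 without wild type replicates 1, 2 and 3. It was 34 with the mouse number as a block, 8 under normexp and 0 with sex as a covariate. Most of the 34 belonged to another pair of tissues: salivary gland and macrophages shared 25 higher and 8 lower genes, small intestine and macrophages 1, and salivary gland and small intestine 0 of their 17. Under normexp salivary gland and small intestine shared 2 of the 17, and they shared 0 without any of small intestine Irgm1-/- replicates 1, 2 and 3 and wild type replicate 3. The count of 2 in all 3 tissues became 0 with the mouse number as a block, 0 with the pancreatic list left out, and 1 with the slide as a block. It was 0 without any of small intestine Irgm1-/- replicates 1, 2 and 3 and wild type replicate 3, and 1 without small intestine wild type replicate 2. It was 0 without macrophage Irgm1-/- replicates 1 and 2 and wild type replicates 1, 2 and 3, and 1 without macrophage Irgm1-/- replicate 3.

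**Figure D3:**
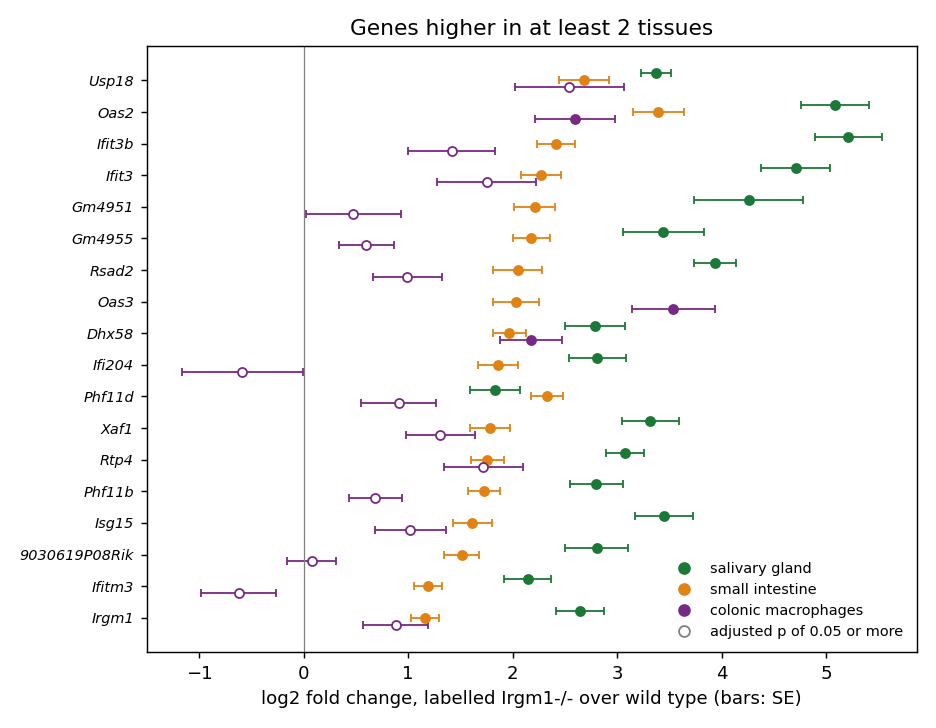
Log2 fold change, Irgm1-/- over wild type, with standard error, in each tissue for the genes past the threshold in at least 2 tissues (4 mice per group in salivary gland, 3 in the other tissues). Ifit3b, Oas2 and Dhx58 were not well above background in wild type salivary gland, so their salivary gland points are fitted values and not bounds; open points did not pass the threshold.

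The difference between tissues was tested directly. Interferon-induced genes had larger effects in salivary gland than in small intestine, with a median difference of 1.52 on the log2 scale over 31 members, of which 14 differed and all 14 were larger in salivary gland. Those 31 of the list's 47 members were bright enough in salivary gland, against 46 in small intestine. A gene can pass that filter through its Irgm1-/- arrays alone, so the members compared may favour larger effects in salivary gland. Genotype also ran together with age in salivary gland and with sex in the other tissues. Differences between tissues cannot be told apart from these. Against macrophages the median difference was 1.26 and 18 of 31 differed, each larger in salivary gland, while small intestine and macrophages had a median difference of 0.10 over 43 members, 2 of which differed. Apol9b (4.57, SE 0.30), Apol9a (3.53, SE 0.29), B2m (3.26, SE 0.30), complement factor B (Cfb, 3.62, SE 0.41) and the class I gene H2-K2 (1.998, SE 0.23) had larger effects in salivary gland than in small intestine. The log2 fold change was lower in salivary gland than in small intestine for Thg1l (difference -6.38, SE 0.33), Derl3 (-1.69, SE 0.31), Asb2, part of a ubiquitin ligase (-3.37, SE 0.62), and Nnt (-1.47, SE 0.29). Of these Nnt and Derl3 fell in salivary gland, and the size for Thg1l rests on wild type levels not above background. The difference of Derl3 ended under normexp (adjusted p = 0.0609), with each array scaled to its median (0.394) and with no filter (0.0596). That of Nnt ended under the same 3 alternatives (0.219, 0.695 and 0.0979) and with the mean of all probes (-0.65, adjusted p = 0.547), as did that of Asb2 with the mean of all probes (-1.14, adjusted p = 0.29). Of 9245 genes tested in both, 76 differed, 72 with the higher signed log2 fold change in salivary gland and 4 in small intestine. This count was 48 without salivary gland Irgm1-/- replicate 2, 46 and 48 without salivary gland wild type replicates 2 and 4, 38 and 44 without small intestine Irgm1-/- replicates 1 and 3, 44 without small intestine wild type replicate 1, and 26 under normexp.

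Salivary gland and macrophages differed in 831 of 9116 genes, 712 with the higher signed log2 fold change in salivary gland. Apol9b (3.79, SE 0.30), B2m (3.07, SE 0.30) and Plac9a (2.35, SE 0.22) had a higher log2 fold change in salivary gland. So did the pancreatic enzymes Prss1 (5.56, SE 0.46) and Cel (6.71, SE 0.60), whose effect lay in macrophages, where they fell. It was lower in salivary gland for Thg1l (-2.41, SE 0.33), Nnt (-1.98, SE 0.29), Rida (-1.15, SE 0.17), Fxyd3 (-1.35, SE 0.22) and Svip (-1.45, SE 0.24), of which Nnt alone changed there. Under normexp Thg1l (-1.01, adjusted p = 0.388) and Rida (0.181) did not pass, and with each array scaled to its median Rida, Fxyd3 and Svip did not (0.406, 0.268 and 0.155). With the mean of all probes Nnt did not (-1.17, adjusted p = 0.0755). Small intestine and macrophages differed in 256 of 13270 genes, 215 with the higher signed log2 fold change in small intestine, or 267 with the animal as a block. It was higher there for Thg1l (3.97, SE 0.36) and for the pancreatic enzymes Cpb1 (9.04, SE 0.87), Cel (6.64, SE 0.65) and Ctrb1 (6.67, SE 0.68), whose effect lay in macrophages. The sizes for Thg1l and Cpb1 rest on levels not above background in 1 genotype. Lower in small intestine were Rida (-1.18, SE 0.20), Svip (-1.56, SE 0.26), the fucosyltransferase Fut4 (-2.14, SE 0.39), Fxyd3 (-1.30, SE 0.24) and the phospholipase Pla2g2f (-2.49, SE 0.47). Under normexp Rida and Fut4 did not pass (adjusted p = 0.183 and 0.122). With each array scaled to its median Rida, Svip, Fut4 and Fxyd3 did not (0.307, 0.136, 0.0567 and 0.315), nor did Fut4 with the deposited series values (0.0603). The count for small intestine and macrophages was 60, 109 and 42 without small intestine Irgm1-/- replicates 1, 2 and 3, and 66 and 66 without wild type replicates 1 and 2. It was 100, 464 and 525 without macrophage Irgm1-/- replicates 1, 2 and 3, and 870, 156 and 97 without wild type replicates 1, 2 and 3.

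Per mouse, the mean of the interferon list stood 2.61 (SD 0.38, n = 4) above the wild type mean in salivary gland (exact two-sided permutation p = 0.0286, the smallest the design allows). It stood 1.26 (SD 0.027, n = 3) above in small intestine and 1.12 (SD 0.22, n = 3) above in macrophages, each with an exact permutation p of 0.1, which is the smallest that 3 against 3 can give.

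**Figure D4:**
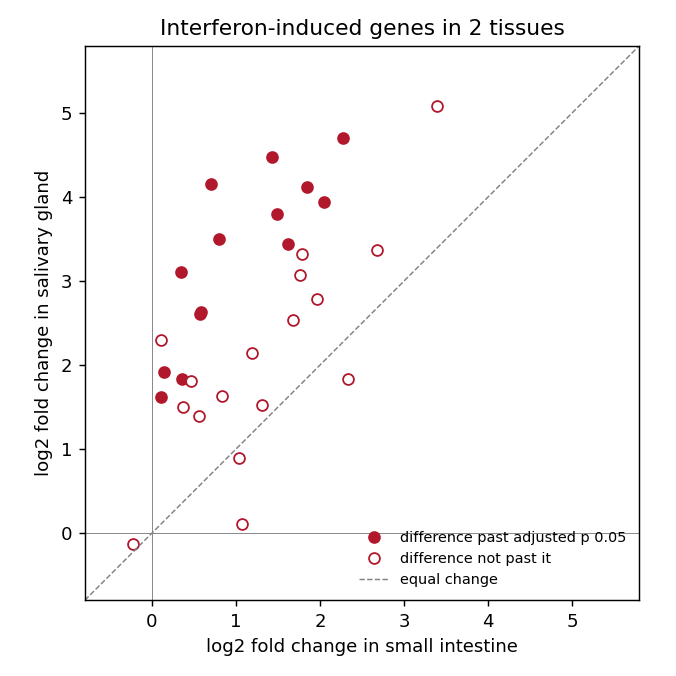
Log2 fold change, Irgm1-/- over wild type, of each type I interferon-induced gene in small intestine (horizontal axis) against salivary gland (vertical axis), with the line of equal change; filled points are genes whose difference between tissues passed the threshold. Of 31 genes tested in both, 28 lay on the salivary gland side of the line, with a median difference of 1.52.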

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

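The tests of the pancreatic genes, of Irgm1 and of the interferon response of Thg1l and the splits by mouse were chosen only after the results were seen, while the other splits of the samples and the test of the neighbours of Irgm1 were planned.

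Pancreatic acinar genes were lower in macrophage samples labelled Irgm1-/- (median -6.24 on the log2 scale over 19 members, of which 10 were also tested in small intestine and 7 in salivary gland). The tables argue against a lower share of epithelium in general, since the general epithelial list differed by 0.54 and the enterocyte list by 0.11, but the stromal list differed by -1.24, so a lower share of muscle and stroma stays open for a part of that size. Pancreatic cells or their RNA in the wild type samples, which the isolation of macrophages should remove, are a candidate source: pancreatic genes outside the list had a median of -4.22 with undetected genes set to their bounds, Amy2a5 at -8.67, Reg1 at least 90-fold and Gp2 at least 49.7-fold lower (already seen), and Ins1 at -2.80 (adjusted p = 0.271), Ins2 at -1.51 (0.567) and Spink1 at 0.42 (0.813) not passing. Sex stays open, because a single Irgm1-/- array is female; its median was -5.93 relative to the lowest wild type array, and with 1 array sex and genotype cannot be told apart. A biological effect of the genotype stays open as well, untested.

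Thg1l was at least 18.1-fold higher in small intestine labelled Irgm1-/- and differed by -0.53 in salivary gland and at least 2.18-fold in macrophages (adjusted p = 0.0507, or 0.0136 with the mouse number as a block and 0.548 under normexp), and Nnt fell by 1.66 in salivary gland (-1.11 with the mean of all its probes, adjusted p = 0.148, not passing) and differed by -0.19 in small intestine and 0.32 in macrophages. The tables argue against Thg1l being part of the interferon response of salivary gland, where it was at -0.529 and the interferon list had its largest median. Induction in the other tissues alone stays open, untested. Thg1l and Pttg1 lie 21 and 35 genes from Irgm1 on chromosome 11 in the reference order. Strain variants carried along with the Irgm1 locus may account for them, but not for Nnt, which is on chromosome 13. Wild type levels of Thg1l were -1.76 to -0.955 in salivary gland, each well above background. They were -6.6 to -6.46 in small intestine and -4.91 to -4.19 in macrophages, none above background. Small intestine and macrophages came from the same 6 mice, of 6 and 8 weeks, so the salivary gland mice of 7 and 9 weeks were others. For Thg1l, tissue and set of mice thus cannot be told apart. A variant whose effect depends on the tissue and a variant of equal effect carried by only some of the mice both stay open. The difference of Pttg1 between salivary gland and small intestine did not pass (limma interaction, adjusted p = 0.1032). A variant elsewhere in the genome stays open for Nnt, untested. Among 200 tested neighbours of Irgm1, 1.5% had an unadjusted p under 0.01 in small intestine against 1.39% of other genes (Fisher's exact test, one-sided, p = 0.531), with 8% against 5.47% in macrophages (p = 0.0852) and 8% against 7.62% in salivary gland (p = 0.46), which decides nothing, so for Thg1l a variant and an effect of the genotype cannot be told apart. Thg1l in small intestine kept its call with sex as a covariate (adjusted p = 0.00431) and among females only (1.34e-06), each resting on 1 female Irgm1-/- array, and age in salivary gland stays open, untested.

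Irgm1 was higher on arrays labelled Irgm1-/- in salivary gland and small intestine (2.64 and 1.16). A single array with the wrong genotype label is argued against, since 0 arrays of these tissues lay inside the range of the other genotype for Irgm1 or the interferon list. Transcript left over from a targeted allele, read by probes outside the deleted part, might account for it: the later and the earlier probe differed by -0.02 in small intestine, which decides nothing while the deleted part is not given in the sources used here. A response of the allele to interferon was not tested apart from this.

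In salivary gland 277 genes changed. Of 35 splits of the 8 arrays only 1, the real one, called as many, and the highest other called 12. This share is under 0.05 and the smallest that 35 splits can give, so it argues against chance without excluding it. The real split is also the split by age (9 weeks against 6 and 7), so it does not set genotype apart from age. In small intestine 28 genes changed (highest other split 0) and in macrophages 39 (highest other 0). These tissues have 10 splits each, of which 1, the real one, called as many, and that is too few for a share under 0.05. Of the 4 splits that part all pairs of mice of the same number, the highest other called 0 in both. For the difference between salivary gland and small intestine (76 genes), 4 of 100 splits were as large, the real one included, a share under 0.05. The highest other split called 158, which points to a structure of the samples: the 3 others as large kept or swapped the real grouping of 1 tissue, and the highest that mixed both tissues called 11. For salivary gland and macrophages (831 genes), 2 of 100 splits were as large, the real one included. The highest other, which mixed both tissues, called 1539, more than the real one, and this too points to a structure of the samples. These splits also took no account of the mouse numbers, which may pair the macrophage samples, so they do not exclude chance. For small intestine and macrophages (256 genes) chance cannot be excluded, with 5 of 100 splits as large, the real one included. The highest other called 778, several times the real count, which points to a structure of the samples, and the highest that mixed both tissues called 687. Those 100 splits regrouped each tissue on its own, although both came from the same 6 mice. Splits that put a mouse on the same side in both tissues (chosen after the result was seen) number 10, too few for a share under 0.05, and gave 256 for the real one and 0 as the highest other, also among the 4 that part all pairs of mice of the same number.

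A closer look is also given to genes whose effect differed between tissues by the interaction test (signed log2 fold change in the first tissue minus that in the second). The sizes for Thg1l and Cpb1 rest on levels not above background in 1 genotype. Between salivary gland and small intestine these were Apol9b 4.57, Apol9a 3.53, B2m 3.26, Cfb 3.62, H2-K2 1.998, Thg1l -6.38, Derl3 -1.69, Asb2 -3.37 and Nnt -1.47. Between salivary gland and colonic macrophages they were Apol9b 3.79, Prss1 5.56, Cel 6.71, Plac9a 2.35, B2m 3.07, Thg1l -2.41, Nnt -1.98, Rida -1.15, Fxyd3 -1.35 and Svip -1.45. Between small intestine and colonic macrophages they were Thg1l 3.97, Cpb1 9.04, Cel 6.64, Ctrb1 6.67, Rida -1.18, Svip -1.56, Fut4 -2.14, Fxyd3 -1.30 and Pla2g2f -2.49.

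In 5 of 158 groups of 4 arrays tested, a single array stood apart from the other 3 by Dixon's ratio (critical value 0.829), and chance does so in about 1 in 20 groups. All lay in wild type salivary gland: replicate 3 for Atic (log2 level 3.53), Cck (-3.28), Elf3 (-2.62) and Gbp3 (-5.07), and replicate 4 for Lpo (4.01).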

How the results depend on the processing

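All alternatives were planned before the data were examined, except the other set of probes behind the percentile and the omission of the pancreatic list, which were chosen after seeing the data. A ratio to a second channel was planned and not run, as the files used here hold 1 channel. Of comparisons of a main result with an alternative, 262 kept their direction and side of the threshold (or stayed within 1.5 times for a count), 100 moved, 18 weakened and 1 strengthened; for single genes and lists 4246 stayed, 603 weakened, 71 strengthened and 44 reversed. Where no reason is given, the cause was not tested. Signal over background limits salivary gland most, where 9594 genes were bright enough to be tested. Scaling to the median moved the median of all genes from 0.06 to 0.18 in salivary gland and from -0.10 to -0.20 in small intestine, where normexp gave -0.19; changes are to be read relative to it.

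Under normexp, 3 genes changed in small intestine, 343 in macrophages (22 higher, 321 lower), 8 in at least 2 tissues and 1 in all 3, and 26 differed between salivary gland and small intestine; the salivary gland split was 176 higher and 43 lower. Irgm1 in small intestine was 1.24 and did not pass. Quantile normalization gave 77 in macrophages, 48 between salivary gland and small intestine and 461 between small intestine and macrophages; the series table gave 60, 46 and 399. Scaling to the median gave 153 in salivary gland, 209 in macrophages, 38 between salivary gland and small intestine, 430 between salivary gland and macrophages and 95 between small intestine and macrophages, with Irgm1 in small intestine at 1.06, not passing. With no filter, salivary gland had 147 genes and 21 lists, 0 genes in all 3 tissues, 39 between salivary gland and small intestine and 108 between small intestine and macrophages, and Irgm1 in small intestine (1.16) did not pass. With detection on every array, where fewer genes are tested, there were 118 in salivary gland, 10 in at least 2 tissues, 0 in all 3, 44 between salivary gland and small intestine and 463 between salivary gland and macrophages. The mean of all probes gave 1 gene in all 3 tissues and Irgm1 in small intestine 1.17, not passing. The fit of all 20 arrays gave 903 in macrophages, 31 in at least 2 tissues and 7 in all 3, with Irgm1 in small intestine (1.16) not passing; an intensity trend with robust variances gave 62 in macrophages. The other set of probes behind the percentile gave 1 in all 3 tissues.

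The mouse number as a block gave 696 in salivary gland (429 higher, 267 lower), 1 in small intestine, 1313 in macrophages, 34 in at least 2 tissues (0 of them in salivary gland and small intestine) and 0 in all 3; Irgm1 did not pass in small intestine (1.16) and passed in macrophages (0.88). In salivary gland no pair of samples of the same number were each other's best match. The slide as a block gave 641 in salivary gland, 1 in all 3 tissues, and Irgm1 in small intestine (1.16) not passing. Sex as a covariate gave 1 in small intestine, 10 in macrophages, 0 in at least 2 tissues and 0 in all 3, and females only, with fewer samples and 1 Irgm1-/- array assumed to vary like the other groups, gave 2, 229, 1 and 0; Irgm1 in small intestine was 1.24 and did not pass in either. Without the pancreatic list 8 genes changed in macrophages and 0 in all 3 tissues. With an estimated correlation 0 lists passed in salivary gland, 0 in small intestine and 0 in macrophages, and the interferon list's medians of 2.60, 1.08 and 0.92 did not pass; fry gave 2 lists in small intestine and 1 in macrophages, where the interferon list (0.92) did not pass. Animal as a random block kept the 3 counts of differences within 1.5 times.

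The following turned direction, none of them past the threshold in the alternative; for lists the direction is that of the test and the value the median. Under normexp this was Cpb1 (-0.81) in small intestine. Under quantile normalization, Cfb (0.0049), Pttg1 (0.0035) and the test of the enterocyte (-0.035) and goblet cell (-0.039) lists in small intestine; with the series table, Cfb (0.0035), Pttg1 (7.2e-05) and the same lists (-0.035 and -0.035). Scaled to the median, Cpb1 (-0.010), B2m (-0.0060) and H2-K1 (-0.087) in small intestine and Asb2 in salivary gland (0.032). With the mean of all probes, Asb2 in salivary gland (0.58), Pttg1 in small intestine (0.17) and Cxcl10 in macrophages (-0.11). With sex as a covariate and in females only, B2m (-0.080) and H2-K1 (-0.027) in small intestine and H2-K1 (-0.012), Ifng (0.22), Nnt (-0.083) and Psmb8 (-0.065) in macrophages. With sex as a covariate, so did the oxidative phosphorylation (-0.0087) and general epithelial (-0.026) lists in macrophages.

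Leaving out each array gave 137 to 382 genes in salivary gland, 2 to 47 in small intestine, 20 to 42 in macrophages, 2 to 29 in at least 2 tissues and 0 to 2 in all 3. Differences numbered 38 to 99 between salivary gland and small intestine and 42 to 870 between small intestine and macrophages. Irgm1 in small intestine ran from 1.12 to 1.21 and the lists in macrophages from 9 to 17. Ranges that crossed 0 were those of Asb2 in salivary gland (-0.26 to 0.026), of H2-K1 (-0.051 to 0.067) and Cpb1 (-0.047 to 0.26) in small intestine and of Gbp2 (-1.01 to 0.10), Ifi204 (-1.06 to 0.024), Irgm2 (-0.31 to 0.37), Cxcl10 (-0.15 to 0.74), Cxcl9 (-0.23 to 0.79) and Iigp1 (-0.12 to 0.71) in macrophages.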

Other observations

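The values below were looked at after the comparisons were seen, apart from the sex genes and the lists, which were planned, and none was tested further.

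In macrophage samples, antimicrobial genes of the Paneth cell list went in both directions without a gene past the threshold: Reg3a, a secreted lectin, was at least 9.93-fold lower (adjusted p = 0.149) and the phospholipase Pla2g2a at least 2.98-fold higher (adjusted p = 0.138), and the list's median was -0.10 (adjusted p = 0.209). B cell and plasma cell markers had a median of 0.68 (0 of 17 past the threshold, adjusted p = 0.0744) and circadian clock genes of -0.25 (0 of 14, adjusted p = 0.0844), with Hlf at -0.98 and Cry2 at -0.95. The versican gene Vcan (-2.18, adjusted p = 0.0659) and Ptgs2, which makes prostaglandins (-2.23, adjusted p = 0.152), were lower without passing. In small intestine, Lct (lactase) differed by -2.93 with an SE of 1.54, the mast cell proteases Mcpt2 and Mcpt1 by -2.51 and -2.26, and Il18 by -1.43, none of them past the threshold.

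The Y-linked gene Eif2s3y was well above background on 4 of 4 female macrophage arrays (intensity 669.5 to 2404) and on 2 of 2 male ones (1256 to 1617), but on 0 of 4 female arrays in small intestine, while Ddx3y was above background on 0 of 4 female arrays in both. Xist was well above background on 1 of 8 salivary gland arrays, all female. Among transcripts without a gene name, 18 of 1929 tested changed in salivary gland (17 higher, 1 lower), 0 of 3014 in small intestine and 1 of 4634 in macrophages (lower).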
